A study of Mus musculus with 137 samples.

How the data were processed

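RNA from cortex and hippocampus was sequenced as 137 libraries of 69 mice. Per the labels' protocols, RNA was extracted with Qiazol and RNeasy 96 columns, poly(A) libraries were made with the NEBNext Ultra II Directional kit, and sequencing gave paired 150 nt reads. Per the submitters' processing notes, FastQC, HISAT2, featureCounts and DESeq2 were used with mm39 (GRCm39), without versions. Groups were taken from the sample labels: the tissue, the line, the genotype, the injection and the labelled dose. Animal numbers in the labels gave the animal behind each library and an earlier and a later series of animals.

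The authors deposited a table of raw gene counts for 57180 genes, in whole numbers, which was the basis of the gene-level tests. They deposited a second table of normalized counts, a signal in which the raw counts of a library are divided by a single factor. That table was used as an alternative scale for the score. The authors also deposited counts of reads aligned to the RTT271 transgene in the treated libraries and to the MECP2 E2 coding sequence in the Tau-line libraries, with total reads, a scale factor and a normalized value. In those files the aligned reads were multiplied by the scale factor, which lay within 1.009 to 1.012 times DESeq2's size factor in 79 libraries, so the aligned reads scaled to a library's gene counts were used instead. The transgene counts cover no PBS-injected or non-injected library, so they have no background. Gene symbols came from the count table, where 7074 genes had none and 27 had symbols turned into dates. The reference annotation at hand was GENCODE M21 on GRCm38, another build than the authors', so it served for gene biotypes and lengths (51884 genes matched) and no coordinate is given.

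Differential expression was tested in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr by group with a minimum count of 10 and a minimum total of 15, estimated dispersions, glmQLFit and the quasi-likelihood F test, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. The 5 groups of the Mecp2 line in a tissue shared 1 fit without covariates, and the Tau line was fitted alone. Differences between tissues were the tissue-by-group interaction with animal as a block. Log2 changes are the first group minus the second, with the standard error from the fit. CPM values are TMM-scaled and given as mean ± SD. The smallest groups tested held 2 non-injected and 6 PBS-injected knockouts. On counts simulated for the knockout comparison in cortex over 24839 genes, 88 of 100 genes changed by 1.5-fold and 98 of 100 changed by 2-fold were called, with 7 unchanged genes. For the Tau line in cortex over 19882 genes the figures were 77, 94 and 6, and for the tissue difference over 3000 genes 46, 64 and 1. The changed genes were drawn from those with an average log2 CPM of at least 1, so recovery of weaker genes is not covered.

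The genes named were chosen by a rule fixed before the data were examined. Mecp2, Mapt, Irak1 and the transgene were always named. For knockouts against wild types and for the Tau line, the 10 largest rises and 10 largest falls were eligible, among protein-coding genes with a symbol, an adjusted p under 0.05, an average log2 CPM of at least 1 and each library of the first group on the same side of the second group's median. For each dose against PBS-injected knockouts, these genes and the 5 largest rises and falls by the same criteria were eligible, and for other comparisons the 5 largest rises and falls. From each gene list up to 4 members with the smallest adjusted p were eligible. Genes shared by knockout and overexpression were taken from these.

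A set of 31 gene lists (pathways, cell types and brain regions) was written before the data were examined. Each was tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the lists of a comparison. Over 16 comparisons 174 of these camera tests passed, and 19 with an estimated correlation. Members called were counted after adjustment over all genes and adjusted over the list alone. Genes of at least 100 kb were tested as a further set.

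The score of a library is the mean log2 CPM of genes called higher in PBS-injected knockouts than in wild types minus that of genes called lower, scaled to a mean of 0 in wild types and 1 in PBS-injected knockouts. Transgene levels were compared between doses as log2 of CPM plus 0.1 by two-sided permutation tests with 1e+05 resamples, or exact ones where a group held fewer than 10 animals. Scores and transgene levels were related by Pearson's r and Spearman's rho within a tissue and dose. Reversal was the count of genes called in knockouts and called the opposite way in a treated group. Since both comparisons use the same knockouts, 8 simulations per tissue without an effect in any group gave chance values of the covariances. In 10 splits of the knockouts into 3 and 3 the shared libraries were removed. Overlaps of calls were set beside the product of both counts divided by the genes tested in both, with Fisher's exact test.

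Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors in edgeR, no filter or a stricter filter of at least 1 CPM, the replicate number as a block, a fit of the compared groups alone, the animal number series as a covariate, pooled non-injected and PBS-injected knockouts, and leaving out each replicate of small groups. Others were added after the data were seen: leaving out 2 Tau-line animals whose Mapt and Mecp2 go against their labels, leaving out 2 hippocampal libraries or their animals with markers of other regions or the hippocampal library of KO_AAV_3e11 replicate 1, and each animal number series alone. No library was left out of the results otherwise, and no pair of libraries was a duplicate. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.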

Results

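Gene expression was measured by RNA sequencing of the cortex and hippocampus of 69 mice, giving 137 libraries. In the Mecp2 line, male wild-type mice injected with PBS (21 per tissue) were set beside male Mecp2 knockouts in 4 states. These were knockouts injected with PBS (6 per tissue), knockouts given the vector AAV9-RTT271 at a labelled dose of 1e11 (13 per tissue) or 3e11 (12 per tissue), and knockouts without an injection (2 per tissue). The vector carries an MECP2 coding sequence, and the labels give no unit for the dose. In a separate Tau line, animals labelled as overexpressing Mecp2 from the Tau (Mapt) locus (7 per tissue) were compared with animals labelled as controls (7 in cortex, 8 in hippocampus). The libraries held 23.2 to 37.8 M gene counts, with a median of 32.1 M. Replicates are numbered within their group (KO_PBS replicate 6 is a PBS-injected knockout), and in the Mecp2 line a replicate number marks the same animal in cortex and hippocampus. The numbers of Tau-line controls differ between the tissues, so there animals were matched by the animal number in the labels. Animal numbers fall into an earlier and a later series. The 3e11 and non-injected animals were from the later series, as was 1 of the 6 PBS-injected knockouts, replicate 6. The 1e11 group held 8 earlier and 5 later animals and the wild types 16 and 5.

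Mecp2 (ENSMUSG00000031393), which encodes the methyl-DNA-binding protein lost in Rett syndrome, separated knockouts from wild types in both tissues. In cortex it stood at 186 ± 18 CPM in wild types (SD, n = 21; 141 to 207) and at 16.1 ± 1.72 CPM in PBS-injected knockouts (SD, n = 6; 12.8 to 17.6). In hippocampus the levels were 208 ± 7.38 CPM (SD, n = 21) and 20.8 ± 5.81 CPM (SD, n = 6). The Mecp2 count was also low in treated knockouts. Cortical levels were 15.8 ± 3.06 CPM at 1e11 (SD, n = 13) and 15.7 ± 3.3 CPM at 3e11 (SD, n = 12), and hippocampal levels 24.2 ± 3.9 CPM and 24.4 ± 3.26 CPM. Irak1 (ENSMUSG00000031392), a kinase gene next to Mecp2 on the X chromosome, stood at 133 ± 11 CPM in knockout cortex (SD, n = 6) against 48.4 ± 3.73 CPM in wild type (SD, n = 21). The treated groups held 133 and 136 CPM of it. No library of the Mecp2 line went against its genotype label.

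**Figure D1:**
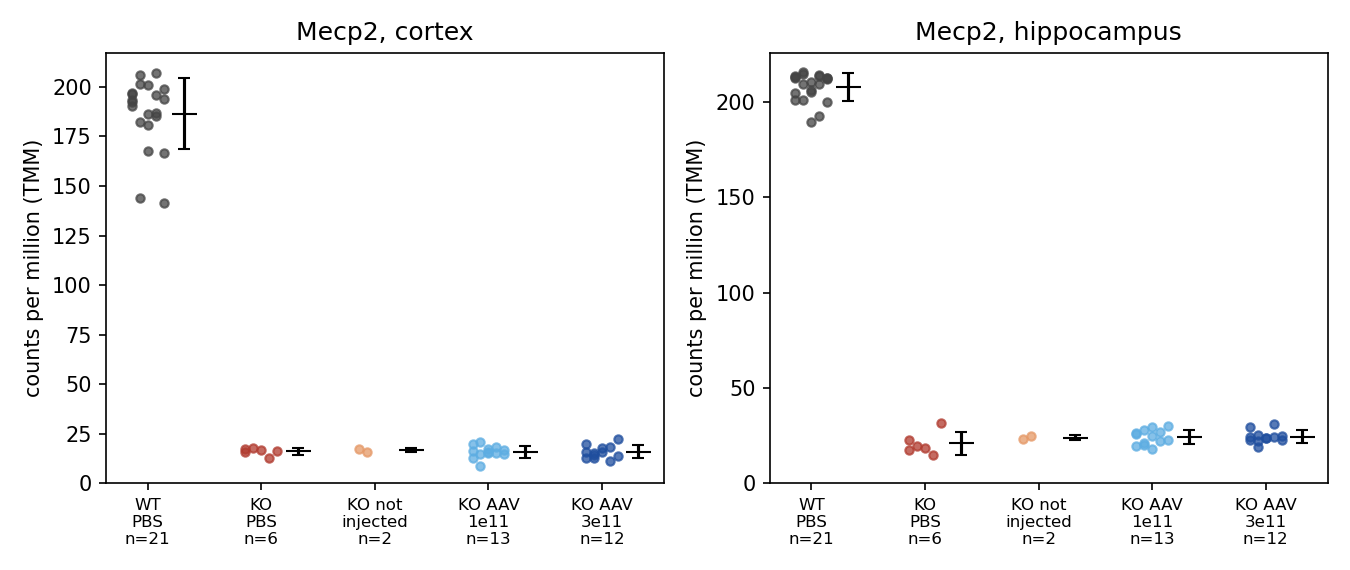
Mecp2 level in CPM for each library of the 5 Mecp2-line groups, in cortex and hippocampus, with the group mean and SD. The wild-type cortices lie between 141 and 207 CPM, and the cortices of the PBS-injected and treated knockouts between 8.45 and 22.3 CPM.

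The effect of Mecp2 loss was taken from PBS-injected knockouts against PBS-injected wild types. In cortex 872 genes were higher and 807 lower in knockouts of 24839 tested. Irak1 rose by a log2 change of 1.46 ± 0.04 (SE, adjusted p = 2.31e-35). It stayed at 133 and 136 CPM in treated cortex, so this rise of a gene next to Mecp2 is not shown to follow the loss of Mecp2 itself. Bmper, a secreted regulator of BMP signalling, rose by 0.97 ± 0.13 (adjusted p = 1.13e-06; 21 ± 2.49 CPM in 6 knockouts against 10.7 ± 1.88 CPM in 21 wild types). Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce, rose by 1.03 ± 0.17 (adjusted p = 3.23e-05). So did the astrocyte enzyme gene Etnppl by 1.42 ± 0.22 (adjusted p = 1.92e-05), Mctp2 by 1.17 ± 0.20 (adjusted p = 0.000103) and the integrin gene Itga11 by 1.04 ± 0.18 (adjusted p = 0.000115). Besides Mecp2, which fell by 3.53 ± 0.13, the falls included the monoamine transporter gene Slc29a4 at −1.83 ± 0.30 (adjusted p = 3.1e-05; 2.17 ± 1.22 CPM against 7.8 ± 3.56 CPM). The troponin gene Tnnc1 fell by 1.49 ± 0.22 (adjusted p = 4.95e-06) and the polarity gene Crb1 by 1.40 ± 0.31 (adjusted p = 0.00241). The kinase-family gene Plk5 fell by 1.33 ± 0.15 (adjusted p = 3.03e-08) and Crh, the corticotropin-releasing hormone gene, by 1.23 ± 0.20 (adjusted p = 4.36e-05). Each gene in this paragraph had its 6 knockout libraries on the same side of the wild-type median.

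Among the gene lists tested in cortex, neuropeptide genes were lower in knockouts, with 8 of 19 measured members called lower and 0 higher (13 and 1 adjusted over the list alone). Their camera adjusted p was 2.97e-07, and adjusted p = 0.000495 with an estimated correlation. They included Crh, Tac1, the substance P precursor, at −1.18 (adjusted p = 0.00024), Pdyn, the dynorphin precursor, at −0.66 (adjusted p = 0.00137) and Tac2 at −0.77 (adjusted p = 0.00151). Of 22 genes described in the literature as Mecp2 targets, 4 were called higher and 2 lower (4 and 3 adjusted over the list alone; camera adjusted p = 4e-05, adjusted p = 0.00019 with an estimated correlation). Oligodendrocyte-precursor markers had 4 of 10 members called lower (4 adjusted over the list alone; camera adjusted p = 4e-05, adjusted p = 0.0639 with an estimated correlation). Among them were Cacng4 at −0.45 (adjusted p = 0.00143) and Gpr17 at −0.46 (adjusted p = 0.0124). Cholesterol synthesis genes had 5 of 23 called lower (8 adjusted over the list alone), among them Cyp51 at −0.41 (adjusted p = 0.00508; camera adjusted p = 0.000272, adjusted p = 0.343 with an estimated correlation). Genes of the unfolded protein response had 6 of 20 called lower (8 adjusted over the list alone; camera adjusted p = 0.000473, adjusted p = 0.343 with an estimated correlation). They included the chaperone genes Pdia4 at −0.59 (adjusted p = 0.00495) and Hspa5 at −0.55 (adjusted p = 0.00674). Glutamate-synapse genes had 6 of 24 called lower and 1 higher (12 and 2 adjusted over the list alone; camera adjusted p = 0.00119, adjusted p = 0.252 with an estimated correlation). The scaffold gene Dlg4 stood at −0.26 (adjusted p = 1.83e-05) and the receptor subunit gene Grin1 at 0.26 (adjusted p = 0.000263).

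Glucocorticoid-responsive genes had 7 of 18 members called higher in knockout cortex (10 adjusted over the list alone; camera adjusted p = 2.76e-05, adjusted p = 0.252 with an estimated correlation). KO_PBS replicate 6 stood apart in them: its cortex held Plin4 at 89.5 CPM and Lcn2 at 11.9 CPM, where the other 5 knockouts reached at most 9.76 and 0.221 CPM. Without replicate 6 the cortical count of called genes went from 1679 to 850, and the glucocorticoid list had 1 member called higher, the precursor list 1 lower, the cholesterol list 0 and the unfolded protein response list 4 lower. Fkbp5 was still higher at 0.49 (edgeR adjusted p = 0.0271) and Etnppl at 0.68 (adjusted p = 0.033), and Bmper, Plk5, Slc29a4, Crh and Tac1 passed without it. Of 42 named calls 14 ended without it, among them those of Plin4 at 0.07 (adjusted p = 0.956), Lcn2 at −0.78 (adjusted p = 0.817), Gpr17 at −0.39 (adjusted p = 0.0807) and Cyp51 at −0.33 (adjusted p = 0.0512). Within the earlier animal number series 647 genes were called, and the later series held 1 PBS-injected knockout, too few for a value.

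In hippocampus 308 genes were higher and 274 lower in knockouts of 25672 tested. The basement-membrane collagen gene Col4a1 rose by 0.68 ± 0.09 (SE, adjusted p = 1.15e-06; 121 ± 14.3 CPM in 6 knockouts against 75.5 ± 6.95 CPM in 21 wild types). The protease gene Prss23 rose by 0.79 ± 0.15 (adjusted p = 0.00223), Fkbp5 by 0.76 ± 0.13 (adjusted p = 0.000268) and Irak1 by 1.36 ± 0.04 (adjusted p = 8.62e-32). Falls included Oprk1, the kappa opioid receptor gene, at −1.82 ± 0.40 (adjusted p = 0.00801; 1.22 ± 0.438 CPM against 4.32 ± 2.07 CPM). The sodium channel gene Scn7a fell by 1.35 ± 0.30 (adjusted p = 0.00768) and the orphan receptor gene Gpr153 by 1.33 ± 0.26 (adjusted p = 0.00254). Cplx3, a complexin of the synaptic release machinery, fell by 1.29 ± 0.29 (adjusted p = 0.0085). Each of these genes had its 6 knockout libraries on the same side of the wild-type median. Without KO_PBS replicate 6, 12 of 29 named hippocampal calls ended, while the genes of this paragraph kept theirs, Fkbp5 at 0.55 (edgeR adjusted p = 0.017).

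Oligodendrocyte-precursor markers in hippocampus had 3 of 10 members called lower in knockouts (7 adjusted over the list alone; camera adjusted p = 2.14e-06, adjusted p = 0.0423 with an estimated correlation). Among them were Gpr17 at −0.45 (adjusted p = 0.0128) and the growth factor receptor gene Pdgfra at −0.37 (adjusted p = 0.0193). Microglial markers had 3 of 16 called lower (6 adjusted over the list alone; camera adjusted p = 2.83e-07, adjusted p = 0.0664 with an estimated correlation), among them the receptor gene Csf1r at −0.26 (adjusted p = 0.0127). Cholesterol synthesis genes had 4 of 23 called lower (5 adjusted over the list alone; camera adjusted p = 2.47e-05, adjusted p = 0.215 with an estimated correlation). Neuropeptide genes had 3 of 19 called lower (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000523, adjusted p = 0.215 with an estimated correlation). Glucocorticoid-responsive genes had 3 of 18 called higher (7 adjusted over the list alone; camera adjusted p = 2.47e-05, adjusted p = 0.279 with an estimated correlation). Without KO_PBS replicate 6 the precursor and microglial lists had 0 members called and Gpr17, Pdgfra and Csf1r lost their calls at −0.42, −0.35 and −0.24 (edgeR adjusted p = 0.0689, 0.0726 and 0.0689). The hippocampal count of 582 rested on single animals. It was 196 without KO_PBS replicate 6, 260 without replicate 4, 273 without replicate 2, 353 without replicate 3 and 990 without replicate 1. Within the earlier series it was 142.

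Plk5 was the gene whose knockout effect differed between cortex and hippocampus, the interaction being −1.58 ± 0.18 (SE, cortex minus hippocampus, log2, adjusted p = 9.4e-08) with animal as a block. It fell in knockout cortex by 1.33, whereas the hippocampal value was 0.24 (adjusted p = 0.388). The interaction test called 1 gene with and 1 without the animal block. Leaving out the 2 animals whose hippocampal libraries held markers of other regions raised the count to 19.

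What the vector did to knockout cortex was asked by comparing each dose with PBS-injected knockouts. At 1e11, 215 genes were higher and 171 lower, and at 3e11, 521 were higher and 475 lower. Of the 807 genes called lower in knockouts than in wild types, 193 were called higher at 1e11 and 386 at 3e11. At 3e11 Slc29a4 rose by 2.02 ± 0.31 (SE, adjusted p = 2.85e-05; 8.84 ± 2.49 CPM in 12 animals against 2.17 ± 1.22 CPM in 6). Crb1 rose by 1.77 ± 0.33 (adjusted p = 0.000427), Tnnc1 by 1.69 ± 0.23 (adjusted p = 3.53e-06), Plk5 by 1.32 ± 0.16 (adjusted p = 4e-07) and Crh by 1.17 (adjusted p = 0.000356). At 1e11 Slc29a4 rose by 1.84 ± 0.31 (adjusted p = 0.000413), Tnnc1 by 1.47 ± 0.23 (adjusted p = 9.72e-05) and Plk5 by 1.19 ± 0.16 (adjusted p = 4.8e-06). Crh rose by 1.13 (adjusted p = 0.00199) and Crb1 by 1.26 (adjusted p = 0.0264). Postn, which encodes the matrix protein periostin, rose at both doses, by 1.79 ± 0.32 (adjusted p = 0.000843) and 1.63 ± 0.32 (adjusted p = 0.000702). Of the 872 genes called higher in knockouts, 142 were called lower at 1e11 and 333 at 3e11. At 3e11 Mctp2 stood at −1.11 ± 0.23 (adjusted p = 0.00133) and Cabp7, a calcium-binding protein gene, at −1.10 ± 0.21 (adjusted p = 0.000587). Bmper stood at −0.82 ± 0.14 (adjusted p = 0.000225; 11.9 ± 3.05 CPM in 12 animals). In these genes each treated library lay on the same side of the knockout median, except 1 of 13 for Crb1 at 1e11. Irak1, beside Mecp2 on the chromosome, did not pass at either dose, with values of 0.01 (adjusted p = 0.978) and 0.03 (adjusted p = 0.825).

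Neuropeptide genes were higher in treated cortex, with 2 of 19 called at 1e11 and 4 at 3e11 (6 and 9 adjusted over the list alone). Their camera adjusted p was 1.53e-06 and 6.85e-06, and adjusted p = 0.0022 and 0.00407 with an estimated correlation. Glucocorticoid-responsive genes had 4 and 6 of 18 called lower (9 and 8 adjusted over the list alone), with camera adjusted p = 1.53e-06 and 4.74e-05, and adjusted p = 0.318 and 0.515 with an estimated correlation. Glutamate-synapse genes had 3 of 24 called higher at 1e11 and 7 at 3e11, with 1 lower at each dose (10 and 11 higher adjusted over the list alone). Their camera adjusted p was 0.000358 and 0.000147, and adjusted p = 0.318 and 0.346 with an estimated correlation. Without KO_PBS replicate 6 the 1e11 count went from 386 to 147, the glucocorticoid list had 0 members called at either dose with edgeR, and Fkbp5, which fell by 0.96 at 3e11, stood at −0.41 (edgeR adjusted p = 0.125). Within the earlier series 68 genes were called at 1e11, no series gave a value at 3e11, and with the series as a covariate 860 genes were called at 3e11, of which 560 were among the 996.

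In hippocampus the vector raised 175 genes and lowered 219 at 1e11, and raised 232 and lowered 334 at 3e11. At 3e11 Oprk1 rose by 2.10 ± 0.42 (SE, adjusted p = 0.00329; 5.24 ± 3.34 CPM in 12 animals against 1.22 ± 0.438 CPM in 6). Vwa5b1 rose by 1.48 (adjusted p = 0.00169), Scn7a by 1.48 (adjusted p = 0.00509) and Gpr153 by 1.47 ± 0.28 (adjusted p = 0.00149). Col4a1 fell by 0.54 ± 0.10 (adjusted p = 0.000668; 83.1 ± 12.5 CPM in 12 animals). Fkbp5 fell by 0.88 ± 0.14 (adjusted p = 0.000136) and the adhesion gene Flrt3 by 0.71 ± 0.12 (adjusted p = 0.000304). At 1e11 Vwa5b1 rose by 1.33 ± 0.28 (adjusted p = 0.00734). Fkbp5 fell by 0.78 ± 0.14 (adjusted p = 0.00124), Arhgef3 by 0.52 ± 0.10 (adjusted p = 0.00309) and Eepd1 by 0.51 (adjusted p = 0.00252). Oprk1 passed at 1e11 at 1.53 ± 0.41 (adjusted p = 0.0418), and this call ended without any 1 of the 6 PBS-injected knockouts, with edgeR adjusted p = 0.0518 without replicate 1 and 0.1 without replicate 2. Mecp2 itself stood at 0.22 (adjusted p = 0.229) and 0.23 (adjusted p = 0.191) against PBS-injected knockouts. It passed at both doses without KO_PBS replicate 5, at 0.37 (edgeR adjusted p = 0.0176) and 0.39 (adjusted p = 0.0136).

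Oligodendrocyte-precursor markers were higher in treated hippocampus, with 3 of 10 called at 1e11 and 2 at 3e11 (6 and 9 adjusted over the list alone). Their camera adjusted p was 2.34e-07 and 5.48e-07, and adjusted p = 0.064 and 0.0751 with an estimated correlation. Microglial markers had 2 of 16 called higher at each dose (6 and 7 adjusted over the list alone; camera adjusted p = 2.34e-07 and 5.48e-07, adjusted p = 0.145 and 0.178 with an estimated correlation). Interferon-response genes had 2 of 19 called higher at 3e11 (8 adjusted over the list alone; camera adjusted p = 0.000239, adjusted p = 0.359 with an estimated correlation). The counts of 394 and 566 genes were 136 and 208 without KO_PBS replicate 4, 186 and 368 without replicate 6, and 259 and 331 without replicate 3. Without replicate 6 the precursor list had 0 members called at either dose with edgeR (3 and 5 adjusted over the list alone; camera adjusted p = 2.35e-05 and 5.12e-05, adjusted p = 0.15 and 0.285 with an estimated correlation). The microglial list then had 0 and 1 called with edgeR (5 and 5 adjusted over the list alone), and the interferon list 1 at 3e11. Within the earlier series 321 genes were called at 1e11, of which 187 were among the 394, and at 3e11 the count with the series as a covariate was 145, of which 116 were among the 566.

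Of the genes called in knockouts, 335 of 1679 in cortex at 1e11 and 719 at 3e11 were called in the opposite direction with the vector, as were 115 and 227 of 582 in hippocampus. Leaving out 1 PBS-injected knockout at a time gave 119 to 323 and 424 to 685 in cortex, lowest without replicate 6, and 46 to 189 and 91 to 324 in hippocampus, lowest without replicate 4. None was called in the same direction, and independent lists would have shared 13, 33.6, 4.5 and 6.48 opposite genes. Both comparisons contain the PBS-injected knockouts, so the correlations of log2 changes across genes, −0.79, −0.77, −0.78 and −0.81, include shared chance. Covariances were −0.143, −0.143, −0.19 and −0.211, where groups simulated without any effect, the knockouts included, gave medians of −0.0922, −0.094, −0.118 and −0.119. At most 1 knockout gene was called per simulation, so the simulations give no chance count of opposite genes. With the knockouts split 3 and 3 so that no library was shared, the median covariances were −0.0544, −0.0552, −0.0753 and −0.0963. The median counts of opposite genes were 24, 88, 1 and 7, against 1.09, 4.47, 0.0594 and 0.14 for independent lists. In those splits the median share of the knockout difference left after treatment was 38.4% in cortex at 1e11 (28.4 to 59.8%) and 20% at 3e11 (8.45 to 39.9%). In hippocampus it was 54.8% at 1e11 (32.4 to 72.7%) and 39.8% at 3e11 (11.5 to 57.8%). This share leaves out Mecp2 and Irak1 and sets treated animals and the other 3 knockouts against the same wild types. Those wild types also entered the choice of genes, so the share still holds their chance deviations. The ranges are over splits of the same knockouts and are not a sampling error.

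A score per library summed up the knockout-called genes, scaled to a mean of 0 in wild types and 1 in PBS-injected knockouts. Cortical scores were 0.262 ± 0.118 at 1e11 (SD, n = 13) and 0.142 ± 0.144 at 3e11 (SD, n = 12), and hippocampal scores 0.285 ± 0.107 and 0.184 ± 0.18. The 2 lowest hippocampal scores at 3e11, −0.17 in replicate 2 and −0.049 in replicate 1, were of libraries with markers of other regions. The difference between the doses did not pass after adjustment in cortex, at −0.12 (two-sided permutation p = 0.033, adjusted over 2 tissues p = 0.066), or in hippocampus, at −0.101 (permutation p = 0.0982, adjusted p = 0.0982). Among later animals, 5 at 1e11 against 12 at 3e11, the cortical difference was −0.178 (exact permutation p = 0.0183) and the hippocampal one −0.15 (exact permutation p = 0.0816). The genes were chosen on the PBS-injected knockouts, so the value of 1 also holds their chance deviations, and replicate 6 alone reached 1.55 in cortex. The 2 non-injected knockouts were not in that comparison. They scored 0.982 and 0.607 in cortex and 0.247 and 0.54 in hippocampus, where 0.247 was of replicate 1, which held markers of other regions. Treated hippocampi reached 0.409 at 1e11 and 0.414 at 3e11. The distance from 1 in hippocampus therefore cannot be read as an effect of the vector alone.

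**Figure D2:**
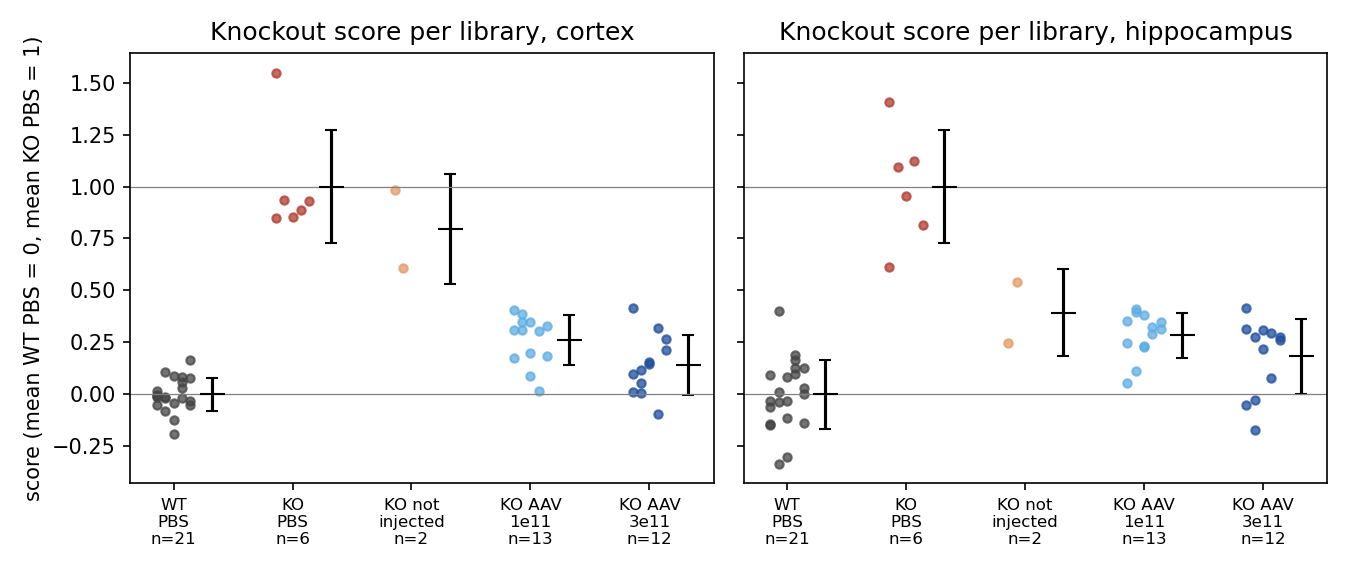
Score of knockout-called genes for each library by group, in cortex and hippocampus, with the group mean and SD. Wild types average 0 and PBS-injected knockouts 1 by construction, and treated cortices average 0.262 at 1e11 and 0.142 at 3e11.

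Against PBS-injected wild types, treated cortex differed in 203 genes at 1e11 (117 higher, 86 lower) and 174 at 3e11 (54 higher, 120 lower), of which 97 and 118 had not been called in PBS-injected knockouts. The knockout comparison held 6 knockouts, and its called genes had a median absolute log2 change of 0.3, against 0.206 and 0.22 here. Genes not called there may thus have changed in knockouts too. Mecp2 and Irak1 were among the 203 and the 174 genes, Irak1 at 1.46 and 1.49. Abca8a, a lipid transporter gene of the ABC family, was lower in each of the 4 treated groups. In cortex it stood at −0.83 ± 0.15 (SE, adjusted p = 0.00206; 3.17 ± 0.684 CPM in 13 animals against 5.63 ± 1.78 CPM in 21) and −0.84 (adjusted p = 0.00194). In hippocampus it stood at −0.82 (adjusted p = 9.59e-05) and −0.98 (adjusted p = 8.53e-06; 5.74 ± 1.41 CPM in 12 animals against 11.4 ± 2.46 CPM). At 1e11 in cortex the cell-cycle gene Ccnd2 was lower at −0.46 ± 0.08 (adjusted p = 0.00179) and Gli1, a hedgehog-pathway factor, higher at 0.78 (adjusted p = 0.0101). Heat-shock genes were lower at 3e11 in both tissues, with 4 of 14 called in each (12 in cortex and 11 in hippocampus adjusted over the list alone). Their camera adjusted p was 2.93e-12 and 2.04e-10, and adjusted p = 0.0131 and 0.0422 with an estimated correlation. Hspa1b, an inducible Hsp70 gene, stood at −0.63 ± 0.14 in cortex (adjusted p = 0.0175; 7.16 ± 1.51 CPM in 12 animals against 11.1 ± 3.55 CPM in 21) and −0.61 in hippocampus (adjusted p = 0.0379). These falls were not separate from the animal number series. With the series as a covariate Hspa1b stood at −0.17 (edgeR adjusted p = 0.913) and −0.18 (adjusted p = 0.85), and within the later series at −0.07 (adjusted p = 0.972) and 0.05 (adjusted p = 0.967). In these fits 0 heat-shock genes were called with edgeR in either tissue, also adjusted over the list alone (3 and 3 of 14 at an unadjusted p under 0.05 with the covariate, 2 and 1 within the later series). Genes still called in the knockout's direction numbered 106 and 54 of 1679 in cortex and 103 and 38 of 582 in hippocampus.

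Hippocampus differed from wild type in 1340 genes at 1e11 (689 higher, 651 lower) and 521 at 3e11 (268 higher, 253 lower), of which 1237 and 481 had not been called in PBS-injected knockouts. The knockout comparison held 6 knockouts, where the treated groups held 13 and 12 animals. The median absolute log2 change of called genes was 0.201 and 0.209 here and 0.413 in the knockout comparison. Genes not called in knockouts are therefore not shown to be unchanged in them. At 1e11 Nkx6-2, an oligodendrocyte transcription factor gene, was higher at 0.78 (adjusted p = 0.00956) and Hapln2, a matrix link protein gene, at 0.66 (adjusted p = 0.0137). Whether the myelin content of the dissections had a part in these values was not tested. At 3e11 the complement gene C4b was higher at 0.77 ± 0.16 (adjusted p = 0.00344; 45.4 ± 23.9 CPM in 12 animals against 26.6 ± 8.03 CPM in 21). Interferon-response genes had 2 of 19 called higher (9 adjusted over the list alone; camera adjusted p = 3.78e-05, adjusted p = 0.216 with an estimated correlation). The striatal genes Six3 and Adora2a were also higher at 3e11, at 2.78 (adjusted p = 0.0156) and 2.18 (adjusted p = 0.00165), with 9 and 8 of 12 libraries above the wild-type median. The hippocampal library of KO_AAV_3e11 replicate 1 held the striatal list 2.22 log2 units above that of wild types. Without it Six3 stood at 1.40 (edgeR adjusted p = 0.317) and Adora2a at 0.96 (adjusted p = 0.144), among 434 called genes, and DESeq2 called neither with it (adjusted p = 0.291 and 0.123). Against wild types of their own series the counts were 28 in earlier and 7 in later cortices and 1089 in earlier and 3 in later hippocampi at 1e11. At 3e11 they were 6 in cortex and 7 in hippocampus. With the series as a covariate the 1e11 counts were 128 and 1245, and the 3e11 counts 20 and 30.

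Genes called in the same direction against both control groups differed from each in the treated animals. Cortex held 3 of them at 1e11 (1 higher, 2 lower), near the 1.01 and 0.592 that independent lists would have shared, and 27 at 3e11 (6 and 21, against 1.13 and 2.29). Hippocampus held 143 at 1e11 (59 and 84, against 4.7 and 5.55) and 67 at 3e11 (19 and 48, against 2.42 and 3.29). Both comparisons contain the treated animals, so they share chance, which these expectations leave out. In cortex at 3e11 Zfp40 was higher against PBS-injected knockouts at 0.66 and against wild types at 0.28, the histone demethylase gene Kdm6a at 0.32 and 0.23, and Atxn1 at 0.25 and 0.16. Plcl1 was lower at −0.76 and −0.50, Ndfip1, an adaptor of ubiquitin ligases, at −0.36 and −0.30, and the phosphatase gene Ppp1cc at −0.35 and −0.22. In hippocampus at 1e11 the oligodendrocyte-lineage gene Sox10 was higher at 0.62 and 0.40, the small heat-shock gene Cryab at 0.76 and 0.41 and Ascl1 at 0.59 and 0.37. Myelin lists of hippocampal libraries without other region markers ranged from −1.2 to 0.72 log2 units around the wild-type median. A part from myelin content in these values was not tested. Hippocampus at 1e11 against wild type had 1089 calls within the earlier series and 3 within the later. Adding the animal number series as a covariate left 9 such genes in cortex and 5 in hippocampus at 3e11.

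Between the doses, hippocampus had 39 genes higher and 159 lower at 3e11 than at 1e11. Ifit3, an interferon-induced gene, was higher at 0.76 ± 0.17 (SE, adjusted p = 0.011; 7.17 ± 2.73 CPM in 12 animals against 4.25 ± 1 CPM in 13). Interferon-response genes had 1 of 19 called higher (8 adjusted over the list alone; camera adjusted p = 1.91e-06, adjusted p = 0.152 with an estimated correlation). Cryab was lower at −0.60 ± 0.14 (adjusted p = 0.0163; 49.7 ± 8.53 CPM against 75.5 ± 20.9 CPM), as was the respiratory-chain gene Cox8a at −0.45 (adjusted p = 0.00652). Cortex gave 0 genes between the doses with edgeR, 1462 at an unadjusted p under 0.05 and 1 with DESeq2. Within the later series 61 genes were called in cortex and 8 in hippocampus, and with the series as a covariate 20 and 0. In cortex the doses shared 192 rises and 126 falls against PBS-injected knockouts, and in hippocampus 68 and 76. Independent lists would share 4.51 and 3.27, and 1.58 and 2.85. Covariances of the log2 changes at the 2 doses were 0.142 and 0.205, where groups simulated without any effect, the knockouts included, gave medians of 0.0934 and 0.118. With the knockouts split between the doses the median covariances were 0.053 and 0.0847.

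Reads of the RTT271 transgene were counted in treated libraries, and no PBS-injected or non-injected library gave a background. Cortex held 28.9 ± 10.8 transgene CPM, reads scaled to the library's gene counts, at 1e11 (SD, n = 13) and 39.9 ± 17.7 at 3e11 (SD, n = 12), a 1.35-fold ratio of geometric means (two-sided permutation p = 0.0869). Hippocampus held 31.6 ± 11.1 and 51.3 ± 22.7, a 1.57-fold ratio (permutation p = 0.0134, adjusted over 2 tissues p = 0.0268). Among later animals the ratios were 1.53 in cortex (exact permutation p = 0.0583) and 1.68 in hippocampus (exact permutation p = 0.0383). Animals high in one tissue were high in the other, with r = 0.815 at 1e11 (permutation p = 0.00104, adjusted p = 0.00104; rho = 0.72, permutation p = 0.00724). At 3e11 r was 0.869 (permutation p = 0.00058, adjusted p = 0.00104; rho = 0.727, permutation p = 0.01). Without the 2 animals farthest from the median these were 0.635 and 0.561.

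Within a dose, cortices with more transgene reads had scores nearer wild type. At 1e11 r was −0.792 (n = 13, permutation p = 0.00088, adjusted over 4 relations p = 0.00176; rho = −0.67, permutation p = 0.0147). At 3e11 r was −0.848 (n = 12, permutation p = 0.00065, adjusted p = 0.00176; rho = −0.699, permutation p = 0.0144). In hippocampus at 3e11 r was −0.695 (permutation p = 0.0106, adjusted p = 0.0141; rho = −0.706, permutation p = 0.0124). The 2 lowest scores there were of replicates 2 and 1, whose libraries held markers of other regions, and the relation was not tested without them. At 1e11 no relation was detected (r = 0.102, permutation p = 0.738, adjusted p = 0.738; rho = −0.187, permutation p = 0.543). Without the 2 libraries farthest from the median of transgene reads, r was −0.734 and −0.59 in cortex, −0.688 in hippocampus at 3e11 and −0.283 at 1e11. Among the 8 earlier animals at 1e11, r was −0.785 in cortex (exact permutation p = 0.0238) and 0.22 in hippocampus (exact permutation p = 0.615). The relation within the 5 later animals was not tested, and the 3e11 animals were of the later series.

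**Figure D3:**
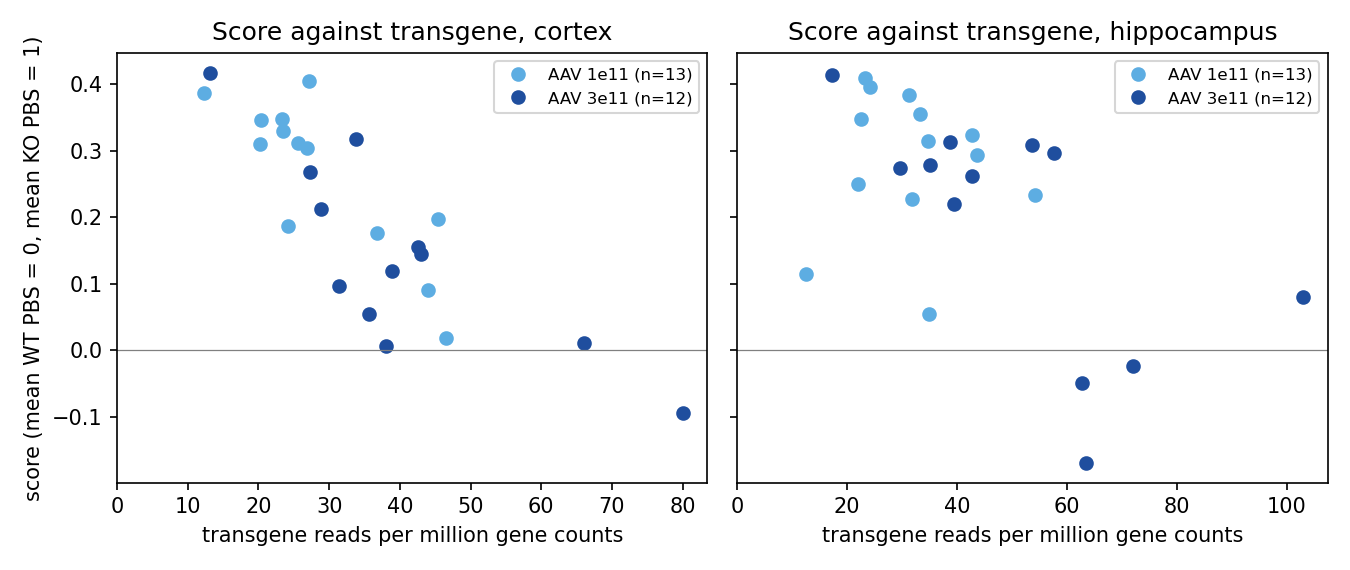
Score of knockout-called genes against transgene CPM for each treated library, by tissue and dose. In cortex the score declines with transgene reads at 1e11 (r = −0.792) and at 3e11 (r = −0.848), and in hippocampus at 3e11 (r = −0.695).

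Knockouts without an injection (2 per tissue) differed from PBS-injected knockouts in genes of neighbouring brain regions. In cortex Penk, the enkephalin precursor gene, was higher at 2.59 ± 0.36 (SE, adjusted p = 1.03e-05) and Tac1 at 2.32, among 32 higher genes and 1 lower. In hippocampus Six3 was higher at 7.45 ± 1.44 (adjusted p = 0.000249), Adora2a at 5.79 and the dopamine receptor gene Drd2 at 4.82, genes known from the striatum, among 1828 higher and 1499 lower. Striatal markers had 9 of 13 called higher in cortex (12 adjusted over the list alone; camera adjusted p = 3.91e-34, adjusted p = 6.31e-05 with an estimated correlation). In hippocampus 12 were called (camera adjusted p = 2.59e-16, adjusted p = 0.0812 with an estimated correlation). Replicate 1 carried them: its striatal list stood 4.3 log2 units above the wild-type median in hippocampus and 2.57 in cortex. Without it Penk stood at 0.80 (edgeR adjusted p = 0.924), Adora2a at 0.22 (adjusted p = 0.999), and 1 gene was called in each tissue. Without replicate 2 the counts were 100 and 5506, and in either case the single animal left was assumed to vary like the other groups.

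In the Tau line, Mapt (ENSMUSG00000018411), the gene of the Tau protein whose locus carries the inserted Mecp2, and Mecp2 itself went against the label in 2 animals. In cortex Mapt stood at 343 ± 3.88 CPM in 6 animals labelled as overexpressing (SD; 338 to 348) and at 668 ± 27.5 CPM in 6 labelled as controls (SD; 644 to 707). The library labelled Tau_OE replicate 7 held 653 CPM of Mapt and 182 CPM of Mecp2, and the library labelled Tau_control replicate 7 held 345 CPM and 225 CPM. In hippocampus the libraries of the same 2 animals, labelled Tau_OE replicate 7 and Tau_control replicate 8, held 648 and 333 CPM of Mapt. With the labels as given, 0 genes passed in either tissue with edgeR, with 1904 in cortex and 1195 in hippocampus at an unadjusted p under 0.05, and DESeq2 called 47 and 0. Mapt then stood at −0.68 in cortex (adjusted p = 0.326) and Mecp2 at 0.24 (adjusted p = 0.356), and in hippocampus both had adjusted p = 0.838. Leaving out the cortical library labelled Tau_OE replicate 7 alone gave 28 genes.

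**Figure D4:**
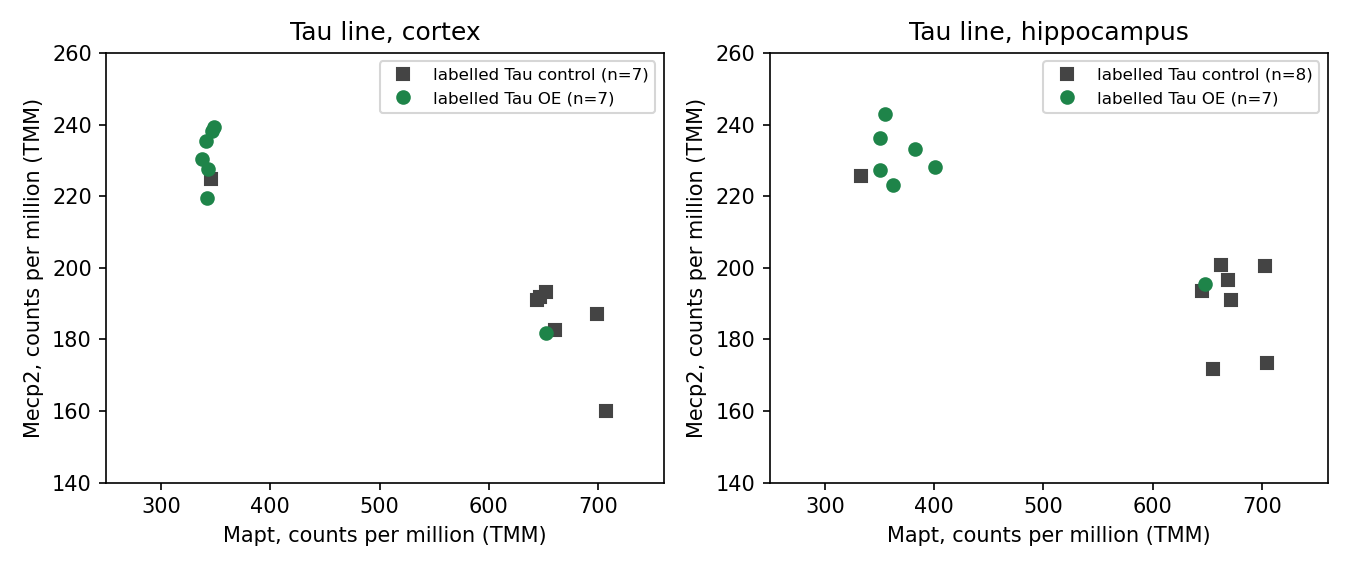
Mapt against Mecp2, both in CPM, for each Tau-line library by label, in cortex and hippocampus. In each tissue 1 library of each label lies among those of the other label, with Mapt at 653 and 345 CPM in cortex and 648 and 333 CPM in hippocampus.

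Without these 2 animals, a choice made after their values were seen, cortex of animals labelled as overexpressing had 195 genes higher and 197 lower, and hippocampus 14 and 7. Mecp2 was 232 ± 7.48 CPM against 184 ± 12.5 CPM in cortex (SD, 6 and 6 animals). No test of Mecp2 or Mapt is given here, since the animals were left out on those values. Cortical rises included Aldh1a3, a retinoic acid synthesis enzyme gene, at 2.09 ± 0.40 (adjusted p = 0.0145). The cytokine gene Clcf1 rose by 1.39 (adjusted p = 0.00952), its partner Crlf1 by 1.47 (adjusted p = 0.0434), Crb1 by 1.42 ± 0.16 (adjusted p = 0.000691) and Postn by 1.25 (adjusted p = 0.00598). Falls included the transcription factor gene Onecut2 at −1.43 (adjusted p = 0.00598), the synaptic organiser gene Cbln4 at −1.04 (adjusted p = 0.00517) and Bmper at −0.96 (adjusted p = 0.00523). In hippocampus Abca8a was higher at 1.10 ± 0.11 (adjusted p = 0.000513; 23.2 ± 2.52 CPM against 10.9 ± 1.83 CPM, 6 and 7 animals) and the T-type calcium channel gene Cacna1g at 0.84 ± 0.13 (adjusted p = 0.0282). Neurofilament and axon genes other than Mapt had 1 of 11 called lower in cortex, Ina (camera adjusted p = 0.164, adjusted p = 0.505 with an estimated correlation). The myelin list had 1 of 20 called lower (median −0.40; camera adjusted p = 5.13e-07, adjusted p = 0.505 with an estimated correlation). The tissue interaction called 0 genes with edgeR with or without the 2 animals (1092 and 1411 genes at an unadjusted p under 0.05).

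Genes called in knockouts were compared with those called in animals labelled as overexpressing, with Mecp2 and Mapt left out. In cortex, without the 2 animals, 197 of 1626 knockout-called genes were called in the opposite direction, and 1404 (86.3%) had the opposite sign, against 61.2% of all genes. Of these, 104 were higher in knockouts and lower in overexpression and 93 the reverse, against 8.35 and 7.62 for independent lists (Fisher's exact p = 5.95e-90 and 2.52e-78). None was called in the same direction. Bmper was higher in knockouts and lower in overexpression, as was Rora, a nuclear receptor gene, at 0.74 and −0.68, while Crb1 went the other way and Cacna1g stood at −0.93 and 0.86. Hippocampus held 8 such genes of 562, 4 in each direction (Fisher's exact p = 6.41e-07 and 1.52e-05), with Cacna1g at −0.88 and 0.84. With the labels as given 0 genes were shared, the Tau comparison having 0 calls with edgeR. Across genes, which are not independent replicates, log2 changes correlated at −0.30 in cortex and −0.25 in hippocampus as labelled, and at −0.35 and −0.29 without the 2 animals.

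**Figure D5:**
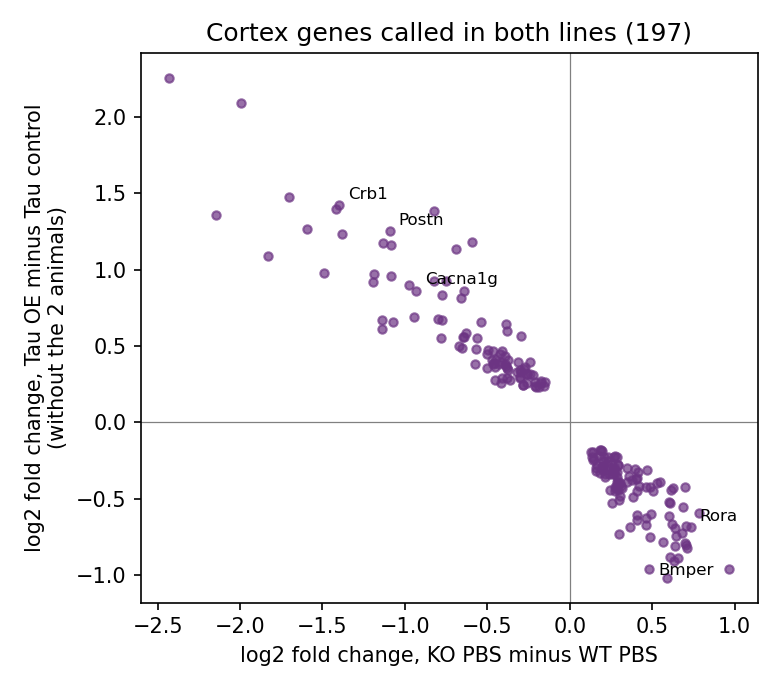
Log2 change in knockout cortex against log2 change in cortex of animals labelled as overexpressing Mecp2, without the 2 animals whose Mapt goes against their label, for the 197 genes called in both comparisons. Each point is a gene, and each of them lies in a quadrant of opposite signs.

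Long genes were compared with shorter ones because length-dependent change is debated in Mecp2 mutants. In knockout cortex the median log2 change of genes of at least 100 kb was 0.03 above that of the rest. It had 240 of 2545 long genes called higher and 109 lower (camera p = 0.0214, p = 0.124 with an estimated correlation). In hippocampus the difference was 0.01 (camera p = 0.49). Treated hippocampus at 3e11 stood at −0.04 (camera p = 0.016, p = 0.0384 with an estimated correlation). The cortex of animals labelled as overexpressing, without the 2 animals, stood at −0.04 (camera p = 0.00141, p = 0.0563 with an estimated correlation).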

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

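Chosen only after the result was seen were the tests on the labels and on mixed RNA of the Tau-line animals and the test of a fault of 1 library. So were the test of tissue from another region in 1 library for the genes called between the doses, and the fits within an animal number series. The fits without the animals with other region markers or without KO_AAV_3e11 replicate 1 were also chosen after it.

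Libraries that stood apart from their group were sought in 155 groups of 6 to 8 libraries, as a gap to the nearest other library beyond the 95% critical value of Dixon's test. Chance flags about 1 in 20 groups, 7.8 here, and 39 were found, 13 of them in libraries of KO_PBS replicate 6 and most of the rest in the 2 Tau-line animals whose Mapt goes against their label. Flagged genes such as Plin4 and Lcn2 were named for their calls in these same libraries. The figure of 7.8 is therefore a rough guide and no test of the 39.

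In cortex, KO_PBS replicate 6 was the highest of 6 for Etnppl (117 CPM, next 35.4), Fkbp5 (187 CPM, next 69.9), Gli1 (5.65 CPM, next 2.78), Plin4 (89.5 CPM, next 9.76), Lcn2 (11.9 CPM, next 0.221), Map3k6 (15.6 CPM, next 3.37) and Grin1 (491 CPM, next 380). It was the lowest for Gap43 (77 CPM, next 139). Its score was 1.55 (next 0.933), and its glucocorticoid-responsive list stood 1.77 log2 units above the wild-type median (next 0.42). In hippocampus it was the highest for Fkbp5 (172 CPM, next 103) and the same list (1.66, next 0.252), and the lowest for Mapt (544 CPM, next 611). Other PBS-injected knockouts stood apart in single values. In cortex replicate 5 had the largest library (35.1 M gene counts, next 29.5 M) and the highest Mctp2 (6.91 CPM, next 3.94) and Itga11 (15.1 CPM, next 5.37), and replicate 4 the lowest Mecp2 (12.8 CPM, next 15.9). In hippocampus replicate 4 had the highest Prss23 (21.6 CPM, next 15).

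The glucocorticoid-responsive genes of KO_PBS replicate 6 were weighed as the first pattern. A fault of 1 library would not reach both tissues. The list stood 1.35 log2 units above the next PBS-injected knockout in cortex and 1.40 in hippocampus, which are separate libraries. The pattern was taken up because the list was high in both tissues, so the result of this test was known in advance. Added tissue from another cell type or region is argued against, because the largest gap of any of the 14 marker lists in both tissues was small. It was that of reactive astrocytes, 0.5 log2 units in cortex and 0.25 in hippocampus. This test looked for an excess and could not show a loss of a cell type. In replicate 6 the microglial list was the lowest of the PBS-injected knockouts, at −0.74 in cortex (next −0.18) and −0.53 in hippocampus (next −0.28). So was the oligodendrocyte-precursor list, at −0.6 (next −0.3) and −0.53 (next −0.48), and a loss stays open. Replicate 6 is the PBS-injected knockout of the later series, yet the highest other library of the line, with later wild-type and treated animals included, reached 0.626 in cortex and 0.612 in hippocampus, so the series alone does not give its level. The design names no group that would explain 1 animal, no biological explanation was tested, and stress, illness or handling of this animal before death stay open.

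In cortex of the Tau line, the library labelled Tau_OE replicate 7 had the highest Mapt of its 7 (653 CPM, next 348), Ina (230 CPM, next 186) and Rora (118 CPM, next 80.5). It had the lowest Mecp2 (182 CPM, next 220), Crb1 (1.08 CPM, next 3.97), Cacng4 (25.5 CPM, next 33.8) and E2 coding sequence (11.5 CPM, reads scaled to the library's gene counts, next 45.8). The library labelled Tau_control replicate 7 had the lowest Mapt (345 CPM, next 644) and the highest Clcf1 (5.36 CPM, next 2.42), Npbwr1 (6.74 CPM, next 2.41), Postn (6.8 CPM, next 2.72) and E2 coding sequence (50.1 CPM, next 14.9). Tau_OE replicate 4 had the highest Aldh1a3 (18.6 CPM, next 7.4). In hippocampus, the library labelled Tau_OE replicate 7 had the highest Mapt (648 CPM, next 401) and Sdk1 (7.16 CPM, next 4.3) and the lowest Mecp2 (196 CPM, next 223), Abca8a (9.14 CPM, next 18.6) and E2 coding sequence (12.4 CPM, next 43). The library labelled Tau_control replicate 8 had the lowest Mapt (333 CPM, next 645) and the highest Abca8a (29.8 CPM, next 13.3) and E2 coding sequence (38.6 CPM, next 16.2).

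These 2 animals, the second pattern, carry values of the other label in both tissues, and their labels may have been exchanged. Of their 12 values of Mapt, Mecp2 and the E2 coding sequence, 12 lay nearer the mean of the other label's animals. The animals were picked on Mapt and Mecp2, so only the E2 coding sequence in the 4 libraries could have gone otherwise. Mixing of RNA from both genotypes as the cause is argued against, since the own label contributed on average 0.6% of the Mapt level over the 4 libraries (−11.2 to 8.1%). Its share of Mecp2 was −5.4, 14.7, 13.8 and 14.6%, where the values lay −0.94 to 0.48 SD from the mean of the other label's animals, and its share of the E2 coding sequence was −2.3, −1.4 and −2.3% in 3 of the libraries. A value that goes the other way is the E2 coding sequence in the hippocampal library labelled Tau_control replicate 8, with an own-label share of 20.5%, which lay 4.16 SD under the mean of 45.2 ± 1.58 CPM (SD) in 6 animals labelled Tau_OE, so a part from the own label in that library stays open. An error in the genotyping, in the naming of the animals or in the deposited labels stays open, no biological explanation was tested, and the animals were left in the comparisons made with the labels as given.

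Differences between the tissues in the effects of the knockout and of the vector were tested as an interaction in edgeR with animal as a block. Of the knockout effect, Plk5 differed at −1.58 ± 0.18 (SE, cortex minus hippocampus, log2, adjusted p = 9.4e-08), with each of the 6 knockout cortices under the wild-type median. Of the effect at 1e11 against PBS-injected knockouts, 7 genes differed. Plk5 stood at 1.32 ± 0.19 (adjusted p = 0.00011; 1.19 in cortex and −0.10 in hippocampus) and Slc29a4 at 1.61 (adjusted p = 0.0464; 1.84 and 0.26), each with its 13 treated cortices above the knockout median. The other 5 were Cdk17 at 0.31, Hibadh at −0.37, Nenf at −0.56, and the noncoding Gm27000 at −0.42 and Gm37861 at 2.18, with adjusted p from 0.0252 to 0.0449. At 3e11, 5 genes differed: Plk5 at 1.43 ± 0.19 (adjusted p = 1.66e-05; 1.32 and −0.09), Slc29a4 at 1.76 (adjusted p = 0.0188; 2.02 and 0.34), Arhgef9 at 0.31 (adjusted p = 0.00595), Timeless at −0.73 (adjusted p = 0.00974) and Aspg at −1.43 (adjusted p = 0.049). Without the animal block Plk5 alone passed among the 7 genes at 1e11, and Plk5, Arhgef9 and Slc29a4 among the 5 at 3e11. Aspg stood at adjusted p = 0.0518 without the 2 animals with other region markers. Cdk17, Hibadh, Nenf, Gm27000, Gm37861, Arhgef9, Timeless and Aspg fall outside the naming rule and were chosen after their values were seen. The effects share the PBS-injected knockouts, so they are not independent.

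The third pattern is the 198 hippocampal genes called between the doses, where the 3e11 animals were of the later series and the 1e11 animals of both. A series difference that wild types share is argued against as the whole cause. Later minus earlier wild types moved these genes by 8.8% of the dose difference (median 0.02 against 0.226 log2 units, 127 of 198 genes with the same sign, permutation p = 0.0446, so a part is not excluded). Wild types got no vector, so they cannot show a series difference confined to treated animals. Within the 1e11 group the later minus earlier difference was larger, with a median of 0.07 (median SE 0.071) against the dose difference of 0.229. There 164 of 198 genes had the same sign and 0 were called with edgeR (smallest adjusted p = 0.692). With the series as a covariate the median of these genes went from 0.229 (median SE 0.05) to 0.197 (0.057) with 198 of the same sign, while 0 were called with edgeR (smallest adjusted p = 0.0574, 2425 of 25672 genes at an unadjusted p under 0.05), as the value fell and its error grew. Against the 5 later 1e11 animals the median was 0.179 (0.066), with 1 of these genes called, and against the 8 earlier ones 0.253 (0.057), with 153. The 198 genes had been called on the dose contrast in these same libraries. Their signs and medians in these refits were thus largely fixed in advance and are no support for a dose effect. Tissue of another region in 1 library is argued against, as 248 genes were called without the 2 libraries with other region markers and 159 without KO_AAV_3e11 replicate 1, which held the highest striatal list of the treated hippocampi. An effect of the dose and a part from the series both stay open.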

How the results depend on the processing

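Chosen only after the results were seen were the fits without the 2 Tau-line animals, without the 2 libraries or animals with other region markers, without KO_AAV_3e11 replicate 1 in hippocampus, and within 1 animal number series, and the neurofilament list without Mapt. Of 311 alternative values of 45 results, 219 stayed the same (counts within 1.5 times, tests on the same side of the threshold), 88 moved, 4 became weaker and 0 reversed. Of 3302 alternative values of 224 named genes and comparisons, 2857 kept direction and side of the threshold, 363 became weaker, 78 stronger and 4 reversed. Where a value below moved, the cause was not tested, except that fits of fewer animals hold fewer samples.

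Values that reversed were Plin4 in knockout cortex within the earlier series (−0.011) and Lcn2 there without KO_PBS replicate 6 (−0.78, where leaving out another animal gave up to 3.75). Tac1 in knockout hippocampus stood at 0.82 with non-injected knockouts pooled, and Hspa1b in hippocampus at 3e11 against wild type at 0.053 within the later series.

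DESeq2 gave 338 genes for 1e11 against wild type in cortex (203 with edgeR), 1 between the doses in cortex (0), 627 for 1e11 against PBS-injected knockouts in hippocampus (394) and 47 for the Tau line in cortex (0). A stricter filter gave 339 for 1e11 against wild type in cortex.

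The replicate number as a block gave, in cortex, 174 genes at 1e11 and 644 at 3e11 against PBS-injected knockouts (386 and 996), 524 and 494 against wild type (203 and 174) and 5 for non-injected knockouts (33). In hippocampus it gave 354 for the knockout (582), 49 and 329 for the doses (394 and 566) and 2059 for non-injected knockouts (3327). Replicate numbers do not pair the groups: residuals of libraries with the same number correlated at −0.013 and 0.033 in the Mecp2 line, against 0.306 for the tissues of 1 animal.

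A fit of the compared groups alone gave 1111 genes for the knockout in cortex (1679), 253 at 1e11 (386) and 0 for non-injected knockouts with edgeR (1137 at an unadjusted p under 0.05), and in hippocampus 303 at 3e11 (566) and 127 for non-injected knockouts. Pooling non-injected and PBS-injected knockouts gave 828 and 1777 for the doses in cortex, and 1040 for the knockout and 890 at 1e11 in hippocampus.

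With the animal number series as a covariate, cortex gave 128 genes at 1e11 and 20 at 3e11 against wild type, 20 between the doses and 109 for non-injected knockouts. Hippocampus gave 145 at 3e11 against PBS-injected knockouts, 30 against wild type and 0 between the doses with edgeR (2425 at an unadjusted p under 0.05). Genes moved away from both control groups at 3e11 were 9 in cortex (27) and 5 in hippocampus (67). Within the earlier series cortex gave 647 genes for the knockout, 68 at 1e11 and 28 at 1e11 against wild type, and hippocampus 142 for the knockout. Within the later series cortex gave 7 and 6 for the doses against wild type and 61 between them, and hippocampus 3, 7 and 8.

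Without the 2 libraries with other region markers the knockout count in hippocampus was 919, and without their animals the tissue difference of the knockout was 19 genes (1). Without KO_AAV_3e11 replicate 1 hippocampus gave 358 genes at 3e11 against PBS-injected knockouts. Without the animal block, so without any replicate block, the tissue difference at 1e11 was 1 gene (7). Without the 2 Tau-line animals the Tau line gave 392 genes in cortex and 21 in hippocampus with edgeR and 857 and 180 with DESeq2, and 197 and 8 genes opposite to the knockout (0 and 0), or 368 and 16 at a threshold of 0.1.

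With the knockouts split 3 and 3 the reversed genes had medians of 24 and 88 in cortex and 1 and 7 in hippocampus. Of the 174 camera tests that passed, 19 passed with an estimated correlation. The neurofilament list in Tau-line cortex without the 2 animals passed with an estimated correlation (adjusted p = 0.00485), and without Mapt, a ground for leaving them out, it did not (adjusted p = 0.505). The gene length difference in knockout cortex had camera p = 0.0898 at 50 kb and 0.124 with an estimated correlation, and as labelled in the Tau-line cortex (main p = 0.0185) 0.192 and 0.202.

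Leaving out 1 animal at a time gave these lowest and highest counts. In cortex they were 850 (without KO_PBS replicate 6) and 1601 for the knockout, 147 (replicate 6) and 369 at 1e11, 708 (replicate 6) and 975 at 3e11, 1 (without non-injected replicate 1) and 100 (replicate 2) for non-injected knockouts, and 0 and 28 (without Tau_OE replicate 7; 9 without Tau_control replicate 7) for the Tau line. In hippocampus they were 196 (without KO_PBS replicate 6) and 990 (replicate 1) for the knockout, 136 (replicate 4) and 432 at 1e11, 208 (replicate 4) and 630 at 3e11, 1 (non-injected replicate 1) and 5506 (replicate 2) for non-injected knockouts, and 0 and 0 for the Tau line with edgeR (929 to 1557 at an unadjusted p under 0.05). Reversed genes numbered 119 (replicate 6) to 323 and 424 (replicate 6) to 685 in cortex, and 46 (replicate 4) to 189 (replicate 1) at 1e11 and 91 (replicate 4) to 324 (replicate 1) at 3e11 in hippocampus. There replicate 2 left 68 and 117, replicate 6 left 49 and 107, and replicate 3 left 134 at 3e11.

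The effect of depth was not tested. In simulated counts at the depth and size of the knockout comparison 88 of 100 genes changed by 1.5-fold were called, and 77 of 100 for the Tau line in cortex.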

Other observations

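The fits within 1 animal number series and without the 2 Tau-line animals were chosen only after the result was seen, and the test of the genes opposite in knockout and overexpression and the splits of the libraries were set before it was seen.

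Other splits of the same libraries into groups of the same sizes were drawn to ask whether chance gives as many called genes: 60 splits for the Mecp2 line, 100 for the Tau line and 24 for the tissue differences of the Mecp2 line, the real split included. Chance is called excluded where the share of splits with as many genes is under 0.05, without adjustment over the comparisons. Chance can be excluded in cortex for the knockout (1679 genes, highest other split 183), for 1e11 and 3e11 against PBS-injected knockouts (386 against 64, 996 against 2), and for 3e11 against wild type (174 against 5). It can be excluded in hippocampus for the knockout (582 against 34), for the doses against PBS-injected knockouts (394 against 5, 566 against 28) and against wild type (1340 against 11, 521 against 31), and for 3e11 against 1e11 (198 against 1). These splits do not keep the animal number series apart, so excluding chance does not exclude the series. With the series as a covariate the 3e11 counts against wild type fell from 174 to 20 and from 521 to 30. The 198 between the doses fell to 0 with edgeR. For 1e11 against wild type in cortex, 2 of 60 splits gave as many (203, highest other 213). That share, 0.0333, is under 0.05, but the split with 213 mixed 4 treated and 9 wild-type animals and does not follow the animal number series. What raised its count was not tested, so chance is not firmly excluded for the 203. For the Tau line without the 2 animals, 392 genes were called in cortex, against at most 16 in the other splits. The animals were left out because their values went against their labels, and the other splits did not repeat that choice. Mecp2 and Mapt are also among the 392. The splits are therefore no fair test there, and chance is not firmly excluded. In hippocampus 2 of 100 splits gave as many (21, highest other 52), a share of 0.02. What raised the split with 52 was not tested, so chance is not firmly excluded for the 21. The tissue differences at 1e11 (7 against 0 with edgeR) and 3e11 (5 against 1) each had a share of 0.0417. That is the smallest share 24 splits can give, so chance is not firmly excluded there. Chance cannot be excluded for the count of 1 gene in the tissue difference of the knockout, since 3 of 24 splits gave at least 1 gene (highest other 1), whatever the p of Plk5 itself. The splits could not test chance where 0 genes were called with edgeR, since any split then gives at least as many: between the doses in cortex (60 of 60, highest other 1), and for the Tau line as labelled in cortex (100 of 100, highest other 10), in hippocampus (highest other 1) and in the tissue difference (highest other 27).

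Some libraries carried markers of other regions. Values here are list means of log2 CPM above the median of wild types of the tissue. In the hippocampal library of KO_AAV_3e11 replicate 2 the hippocampal subfield list stood at −2.49 and the cortical layer list at 0.81 (others in the tissue at most 0.39). In the hippocampal library of KO_noninjected replicate 1 the striatal list stood at 4.3 (others at most 2.22), the myelin list at 2.04 (others at most 0.72) and the hippocampal subfield list at −2.09. Its cortex held the striatal list at 2.57 (others at most 0.46). The next highest striatal list, 2.22, was that of the hippocampal library of KO_AAV_3e11 replicate 1 (others of its group at most 0.65). These libraries stayed in the comparisons of the report. In non-injected hippocampi, 10 of 12 thalamic genes (camera adjusted p = 5.23e-08, adjusted p = 0.215 with an estimated correlation) and 18 of 20 myelin genes (camera adjusted p = 8.65e-18, adjusted p = 0.175) were called higher than in PBS-injected knockouts.

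More lists passed camera with the preset correlation and not with an estimated one. In knockout cortex these were heat-shock genes (0 called higher and 1 lower of 14, 0 and 4 adjusted over the list alone; camera adjusted p = 0.000272, adjusted p = 0.252 with an estimated correlation) and neurofilament genes (3 of 12 lower, 4 adjusted over the list alone; adjusted p = 0.0029 and 0.189). In knockout hippocampus the meningeal list had 2 of 15 lower (4 adjusted over the list alone; adjusted p = 6.15e-05 and 0.367). At 3e11 against PBS-injected knockouts in cortex respiratory-chain genes had 3 of 25 lower (7 adjusted over the list alone; adjusted p = 5.01e-05 and 0.515). At 1e11 against wild types in cortex genes of the unfolded protein response had 1 lower (9 adjusted over the list alone; adjusted p = 8.28e-08 and 0.205). At 1e11 against PBS-injected knockouts in hippocampus the myelin list had a median of 0.37 (adjusted p = 2.61e-05 and 0.56). Without the 2 animals, Tau-line cortex had 1 of 10 oligodendrocyte-precursor genes higher (6 adjusted over the list alone; adjusted p = 0.00274 and 0.505), 1 glutamate-synapse gene higher (6 adjusted over the list alone; adjusted p = 0.00077 and 0.505) and 3 of 18 neighbours of Mecp2 on the X chromosome, Flna, L1cam and Plxna3 (4 adjusted over the list alone; adjusted p = 0.012 and 0.505). Its hippocampus had the choroid plexus list at a median of 1.47 with 0 members called with edgeR (adjusted p = 1.24e-07 and 0.495).

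The E2 coding sequence, with the labels as given, averaged 44.1 ± 14.6 CPM in 7 cortices labelled Tau_OE and 17.7 ± 14.4 CPM in 7 labelled Tau_control (SD), and 40.5 ± 12.5 and 16.3 ± 9.15 CPM in hippocampus. Without the 2 animals the means were 49.6 and 12.3 CPM in cortex and 45.2 and 13.2 CPM in hippocampus. The level in animals labelled as controls is the background of this count.

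Genes that follow the amount of Mecp2 in both directions may be brought back by the vector more often than other knockout genes. In cortex, 173 of the 197 genes called in opposite directions in knockout and overexpression (87.8%) were called back at 3e11, against 525 of 1428 other knockout-called genes (36.8%). In 10000 draws of other knockout-called genes matched on the knockout p in 10 bins, the median was 54.3% and the highest 65.5%, so the permutation p was 1e-04, the smallest these draws can give. The draws were matched on the knockout p alone, the Tau-line calls leave out the 2 animals, and the knockout and vector comparisons share the PBS-injected knockouts, and genes called in a separate line are less often chance calls of the knockout comparison, which matching on p does not remove. What the result leaves open is whether such genes respond directly to Mecp2.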
